A study of Mus musculus with 18 samples.

How the data were processed

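The 18 samples of the series were RAD21 and NIPBL ChIP-seq libraries and their inputs from a v-Abl transformed mouse pro-B line (JH-deleted, dCas9-expressing, Eμ-Bcl2, RAG2-deficient). Per the labels' protocols, cells were kept in 3 uM STI-571 for 4 days and fixed in 1% formaldehyde, chromatin was sonicated, and 5 ug of antibody was used. The 14 immunoprecipitated libraries had peak lists, and the 4 inputs were not used here. Groups and replicate numbers were taken from the sample labels: RAD21 dCas9 control (2) and block (2), RAD21 Ig2b wild type (3) and deleted (3), NIPBL dCas9 control (2) and block (2). Nothing in the labels says that replicates come from separate cultures, so each p measures only the spread between these samples.

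Per the submitters' processing notes, reads were aligned to mm9 with Bowtie2 2.2.8, handled with SAMtools 1.8, and peaks were called with MACS2, whose version and settings were not given. Each list was a broadPeak table of 9 columns without a header, and peaks were called per library, not on pooled reads. The fold of each peak is a ratio made by the authors with MACS2, its enrichment over the background estimate. It is the authors' own value and was used only to describe and rank peaks. Folds of different lists were not put on 1 scale. The authors' lists give −log10 p and −log10 q for each peak, as MACS2 deposited them. The score column holds 10 times −log10 q cut to a whole number by the authors' caller, which was checked against the q column, and it was not used. Per the peak names in the lists, the RAD21 dCas9 and NIPBL lists were called against a control library, while the Ig2b lists named none and had duplicates taken out. The RAD21 dCas9 lists had one style of names in both replicate 1 libraries and another in both replicate 2 libraries, which was treated as a technical batch. Read depth per library was unknown, so no interval or floor that needs it was given; only presence and length of called peaks could be compared.

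Coordinates were read on mm9 (NCBIM37) with GENCODE vM1, and the ends of the peaks were checked to lie within its chromosomes. Analysis used 19 autosomes and X. Covered bp is the union of a library's peaks at the authors' threshold. For the genome-wide comparisons, windows of 10 kb with a mean of at least 500 covered bp over the libraries compared were tested on log2 of covered bp plus 500, without normalization between lists, with limma 3.58.1 in R 4.3.3 (two-sided moderated test, Benjamini-Hochberg over the windows tested, adjusted p under 0.05). Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

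Igh was divided into 17 segments and 15 other loci were added, with approximate ends set from the known order of the locus. Sg1 was assigned to the Cγ1 segment and Ig2b to the Cγ2b segment. Their covered shares were compared with exact two-sided permutation tests over all splits of the libraries, adjusted over the Igh segments; the smallest p allowed is 0.333 for 2 against 2 and 0.1 for 3 against 3. For some differences the text gives the place among tiles of the same length with a peak in the libraries compared. Regions were peaks of the libraries compared, merged where they overlapped; a region was gained or lost when every library of one group and none of the other had a peak with at least 1 bp in it. Co-occupancy was the share of NIPBL regions in both controls that overlapped a RAD21 region in both controls by at least 1 bp, against 100 circular shifts (seed 7). CTCF cores were matches of an 11 bp consensus on either strand. Peaks within 5 kb of an annotated start were assigned to genes, and 7 lists with 83 genes (early B lineage, cohesin and CTCF, v-Abl withdrawal, T cell, myeloid, erythroid, housekeeping) were compared with other genes by Fisher's exact test. Spib stood in 2 of the lists. Values of some single genes are not reported here. Named regions followed a fixed rule: every segment and locus, up to 5 called windows per direction, and every gained or lost region in Igh outside the VH segments, with 2 to 4 genes of highest fold per list. Lrp12, the chromosome 12 flanks, the VH window called with quantile normalization and the regions outside Igh named under other observations were chosen after their values were seen.

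The groups, tests, segments, lists, named-region rule and the alternatives listed next were set before the data were examined. The listed settings were replicate number as a block, lists matched in length (58837, 63052, 44729 and 45697 peaks), −log10 q of at least 3, quantile normalization, 100 bp added, no filter, windows of 50 kb, segment ends moved by 3 kb, 50% overlap, all 10 RAD21 libraries in one fit, and leaving out each library. The replicate block combined with other settings was added later. Where leaving out a library left 1 in a group, limma pooled the spread and the lone library was assumed to vary like the others.

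Whether numbers pair libraries was checked by correlating, across windows, each library's deviation from its group mean. In the RAD21 dCas9 set libraries of the same number had r 0.794 and also shared a naming style. In the NIPBL set r was 0.206, with nothing but the number shared. In the Ig2b set the 3 same-number values were 0.0473, 0.145 and 0.215, against −0.184 to 0.0399 between different numbers. The numbers were not taken as pairs in the main fit, though a weak pairing is not excluded. Windows are not independent replicates.

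The window test was tested on simulated data with 200 changed windows and, for each window, the spread that limma had moderated. For RAD21 block against control it recovered 0% of windows changed by a log2 of 1 or 2 and 65.5% of those changed by 3, and with the replicate block 46.5%, 100% and 100%. For NIPBL it recovered 0%, 98% and 99.5%, for the Ig2b deletion 12%, 98% and 100%, for the wild type against control 0%, 78% and 99%, and for the interaction 0%, 0% and 44.5%. Up to 16 unchanged windows were called without the block and up to 33 with it. The moderated spread varies less between windows than the spread of the libraries. Noise was drawn independently for each window, so deviations shared across windows were left out, apart from the replicate shifts in the block fits. Recovery in the real lists may therefore be lower, and 0 calls do not exclude changes of these sizes.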

Results

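RAD21, a subunit of the cohesin ring, and NIPBL, the factor that loads cohesin onto chromatin and drives loop extrusion, were mapped by ChIP-seq in a mouse pro-B cell line transformed by the v-Abl kinase. The line lacked RAG2 and the JH segments, carried an Eμ-driven Bcl2 transgene and expressed dCas9, a Cas9 that binds DNA without cutting it. Cells were treated with 3 uM STI-571, an Abl kinase inhibitor that stops their cycling, for 4 days. Peak lists of 14 libraries fell into 6 groups. RAD21 was mapped in dCas9 control cells (n = 2), in cells that also carried a guide RNA named for Sg1 (block, n = 2), and in an Ig2b experiment with wild type (n = 3) and deleted (n = 3) cells. NIPBL was mapped in dCas9 control (n = 2) and block (n = 2) cells. Sg1 was read as the Sγ1 switch region of the Igh locus and Ig2b as the γ2b I promoter region, since neither the guide sequence nor the deletion ends were given. RAD21 lists held 44783 to 82776 peaks that covered 11.6 to 34.4 Mb, and NIPBL lists held 63153 to 123573 peaks that covered 20.3 to 29.8 Mb. The number of reads behind each list was unknown, so coverage by called peaks, not read density, was compared.

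The first question was where cohesin and its loader lay in control cells. Within Igh, RAD21 peaks covered 30.5% ± 21.6 of IGCR1 (the CTCF-bound control region between the DH and VH segments), 15.95% ± 5.87 of the 3'CBEs (the CTCF sites past the 3' end of Igh) and 7.76% ± 2.31 of the middle and distal VH segments (SD, n = 2 here and for the other control values). NIPBL peaks covered 0.570% ± 0.806 of IGCR1 and 0.574% ± 0.00579 of the middle and distal VH segments, against 20.8% ± 6.96 of Cμ-Sμ and 5.55% ± 0.648 of Cγ1. No match of the 11 bp CTCF core motif used here lay in IGCR1. RAD21 also covered other segments with at most 1 match, with a wide spread between the controls: Cμ-Sμ 28.3% ± 40.1 (0% in replicate 1, 56.7% in replicate 2), Eμ-JH 19.7% ± 20.4, and Cγ2b 0.841% in replicate 1 and 35.2% in replicate 2. The line lacked the JH segments and carried an Eμ-driven transgene. Values for Eμ-JH, here and below, may thus be lowered by missing DNA or include reads from the transgene, which was not tested. Each of the 3 CTCF core motifs in the 3'CBEs lay in a RAD21 region present in both controls, as did 15 of 17 in the proximal VH segments and 53 of 69 in the middle and distal VH segments. Across the genome 8929 of 31746 core motifs (28.1%) did, and at the protocadherin cluster (Pcdh) 0 of 27 did. RAD21 regions without NIPBL held a CTCF core in 22.1% of cases (n = 35698 regions, Wilson 95% interval 21.7 to 22.5), RAD21 regions overlapping NIPBL in 13.9% (n = 5895, 13.0 to 14.8), and NIPBL regions without RAD21 in 0.510% (n = 25884, 0.430 to 0.604). Annotated starts of transcription lay within 5 kb of 49.5% of the RAD21 regions that overlapped NIPBL and 15.3% of those that did not.

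Of 32156 NIPBL regions present in both control libraries, 19.5% overlapped one of 41593 RAD21 regions present in both, against 1.84% ± 0.0935 (SD over 100 circular shifts). The one-sided permutation p was 0.0099, the smallest that 100 shifts allow. The share depended on which libraries defined the regions: it was 44.3% without RAD21 dCas9 control replicate 1, 9.42% without NIPBL dCas9 control replicate 1 and 11.1% without NIPBL dCas9 control replicate 2.

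**Figure D1:**
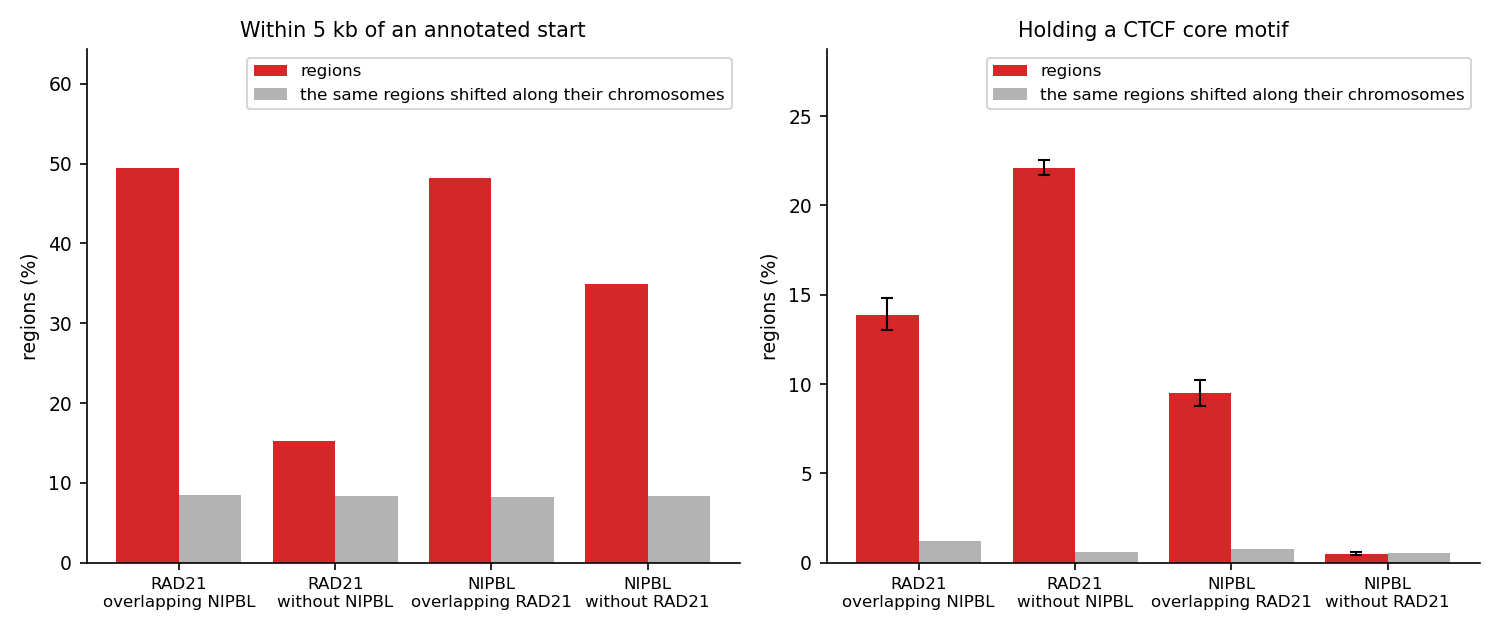
Share of regions (%) within 5 kb of an annotated start (left) or holding a CTCF core motif (right), for RAD21 and NIPBL regions present in both dCas9 control libraries; grey bars are the same regions shifted along their chromosomes and black bars on the right are Wilson 95% intervals. CTCF cores lay in 22.1% of the RAD21 regions without NIPBL and in 0.510% of the NIPBL regions without RAD21.

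Gene lists fixed in advance were then compared with the peaks within 5 kb of their starts. Of 20 early B lineage genes, 18 had a RAD21 peak in both control libraries, against 34.2% of other genes (Fisher's exact test, two-sided, adjusted over the 7 lists, p 2.54e-06), and 18 had a NIPBL peak in both, against 56.5% (exact adjusted p 0.00836). Across the 6 groups 18 to 20 of these 20 genes had a peak in every library of the group. The highest RAD21 folds among them were at Rag1 (13.6 ± 4.88), Ebf1 (7.48 ± 2.74), Foxo1 (7.24 ± 5.11) and Pax5 (6.71 ± 0.188), and the highest NIPBL folds were at Ikzf3 (8.28 ± 0.0166) and Vpreb1 (8.25 ± 0.355; SD, n = 2 each). Genes that respond to v-Abl withdrawal had RAD21 peaks in both controls for 14 of 15 (exact adjusted p 1.09e-05), with Ccnd2 (14.8 ± 5.66) and Cish (14.5 ± 5.58) highest. They had NIPBL peaks for 15 of 15 (exact adjusted p 0.00187). Cohesin and CTCF genes had RAD21 peaks for 8 of 14 (exact adjusted p 0.178; Smc3, 10.95 ± 6.29, and Pds5b, 10.5 ± 0.532) and NIPBL peaks for 13 of 14 (exact adjusted p 0.0128). Among T cell markers, 1 of 9 (Gata3, 5.89 ± 0.0727) had RAD21 peaks in both controls, among myeloid markers 2 of 8 (Elane and Fcgr3), among erythroid markers 4 of 8 (with Klf1, 10.6 ± 5.18, highest) and among housekeeping genes 6 of 10 (Gapdh, 12.1 ± 4.84). In the same order NIPBL peaks lay at 5, 6, 3 and 9 genes. None of the 83 listed genes gained or lost a peak near its start with the block or the deletion. Such changes were rare among all 22208 genes, so this says little about the listed ones. With the block 79 genes gained and 21 lost a RAD21 peak, and 343 and 260 a NIPBL peak. With the deletion 150 gained and 5 lost a RAD21 peak.

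The second question was whether dCas9 at Sγ1 changed where cohesin lay. A RAD21 peak lay over Sγ1 in both block libraries and in neither control, on chromosome 12 from 114572792 to 114575421 (mm9, intergenic, 4058 to 6687 bp upstream of the annotated start of Ighg1). Peaks covered 2630 bp of this region in block replicate 1 (fold 5.42) and 2478 bp in block replicate 2 (fold 6.12), or 97.1% ± 4.09 (SD, n = 2), and 0 bp in the 8 other RAD21 libraries, the 6 of the Ig2b experiment included. Among the 1475 regions gained with the block it ranked 1 by covered bp and 1 by fold, and the next by bp, at the start of Lrp12, had 489 bp. A second, smaller gained peak lay from 114576664 to 114576933 (fold 3.08 to 4.36), and no other region of Igh was gained. Coverage of the whole Cγ1 segment rose from 2.84% ± 2.35 to 10.0% ± 0.634 (SD, n = 2 each), by 7.18 points. The difference was 9.29 points between the replicate 1 libraries and 5.07 points between the replicate 2 libraries, and 24 of 44477 genomic tiles of the same length rose as much. With both segment ends moved in by 3 kb the difference was 11.03 points.

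Coverage of the other Igh segments did not rise beyond the spread between libraries: 15 of 17 overlapped between block and control, against a chance share of separated segments of 0.333. RAD21 covered 20.0% ± 4.57 of IGCR1, 14.4% ± 3.11 of the 3'CBEs and 16.6% ± 11.7 of Eμ-JH in block cells, and 30.5% ± 21.6, 15.95% ± 5.87 and 19.7% ± 20.4 in controls. The proximal VH segments were lower (2.91% ± 0.535 to 1.93% ± 0.641), by −0.146 points within replicate number 1 and −1.81 within number 2. Outside Igh 1 of 15 loci, β-globin, was higher without overlap (1.74% ± 0.129 to 2.44% ± 0.265). Coverage of Cμ-Sμ and Cγ2b in controls rested on 1 library: Cμ-Sμ had 56.7% in control replicate 2 and 0% in control replicate 1, and Cγ2b had 35.2% and 0.841%. Across all VH segments block replicate 2 had 61450 covered bp and control replicate 2 had 205153, a ratio of 0.300 where that of the genome was 0.916; 0 of 1044 tiles of the same length fell as low. The flank of Igh toward the telomere had a ratio of 0.376 in the same pair, where control replicate 2 had 1.44 times the coverage of control replicate 1 relative to the genome. Relative to the genome, block replicate 2 had 0.177 to 0.327 of the VH coverage of the 9 other RAD21 libraries and 0.405 to 0.631 of their coverage of that flank. Replicate 1 had a VH ratio of 1.19 against 1.49 for the genome, and 40 of 1052 tiles fell as low.

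**Figure D2:**
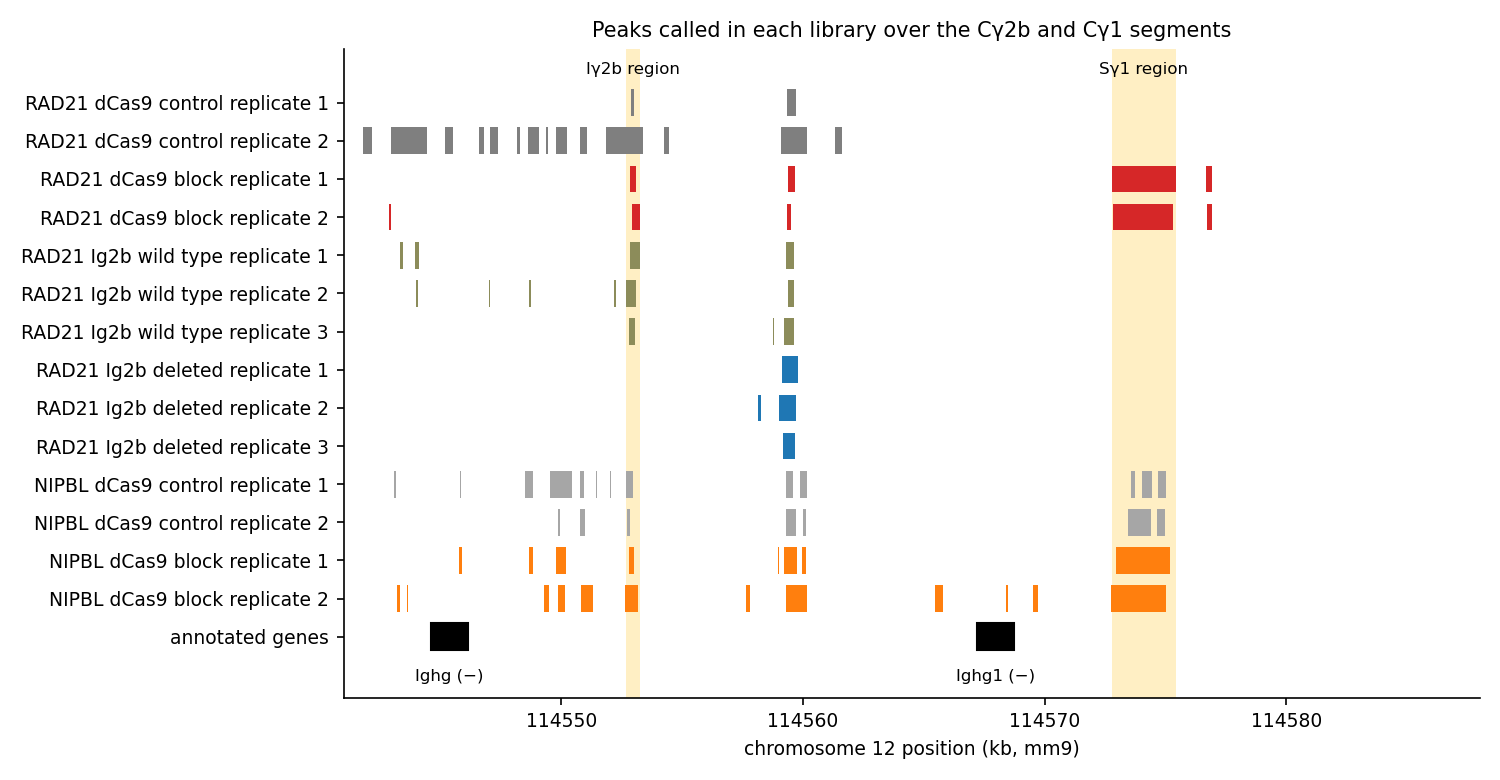
Peaks (boxes) called in each of the 14 libraries along the Cγ2b and Cγ1 segments of Igh; the horizontal axis is the position on chromosome 12 in kb and each line is 1 library. The Sγ1 region is covered in both RAD21 block libraries and 0 of the 8 other RAD21 libraries, and the Iγ2b region in every library except the 3 deleted ones.

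Over the genome, 16780 windows of 10 kb were tested with limma (two-sided). None passed an adjusted p of 0.05, and 3 had an unadjusted p under 0.05. The Sγ1 window ranked 1, with 0 covered bp in both controls and 2870 and 2708 bp in the block libraries (log2 difference 2.72, SE 0.32, limma adjusted p 1, higher in 2 of 2 block libraries). This log2 value depends on the 500 bp added to each window and was 4.85 with 100 bp. Libraries of 1 replicate number shared a style of peak names and resembled each other across the genome: the 4 libraries split by number gave 6196 windows under an adjusted p of 0.05. With the replicate number as a block, the Sγ1 window was the only 1 called (log2 2.72, SE 0.27, limma adjusted p 2.45e-06). In that fit 557 windows had an unadjusted p under 0.05. It had 1 residual degree of freedom and borrowed 25.8 from other windows, against 2 and 2.53 without the block. The Sγ1 window was also the only window called when all 10 RAD21 libraries shared the fit (limma adjusted p 0.00148, SE 0.17). There the 6 Ig2b libraries all had 0 bp in the Sγ1 window and so added no spread. In windows of 50 kb its log2 difference was 0.89 (SE 0.74) and its rank 284. Its adjusted p ranged from 2.45e-06 to 1 over the alternatives, and it was called in 5 of 16. For Cγ1 coverage the exact two-sided permutation p was 0.333, the smallest that 2 against 2 allows, and 1 after adjustment over the list alone.

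Gained and lost regions numbered 1475 and 355 of 127860, 1830 together, fewer than the 20823 and 1904 of the other ways to split the 4 libraries. The split that gave 20823 was again the one by replicate number. The excess of gains was absent with lists matched in length (633 gained, 600 lost) and at a stricter threshold (275 gained and 303 lost, 578 together). Leaving out any 1 of the 4 libraries gave 13068 to 25482, since fewer libraries then had to concur. A CTCF core lay in 4.75% of the gained and 3.10% of the lost regions. Of the 355 lost regions 25 (7.04%) lay in the VH segments, which held 0.512% of all regions, and 0 gained regions did; block replicate 2 had low coverage of VH as a whole (ratio 0.300), and of the flank past it.

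The third question was whether the loader changed at the same place. NIPBL was present over Sγ1 without the block. Its peaks covered 42.9% ± 9.38 of the Sγ1 region in controls (fold 3.39 to 4.26) and 84.8% ± 0.108 in block cells (fold 8.11 to 11.2, SD, n = 2 each). Folds were not put on 1 scale between lists: the median over all peaks was 2.91 to 2.98 in controls and 2.83 to 3.77 in block libraries. At a stricter threshold the control coverage was 3.86% ± 5.46, with a peak in 1 of 2 controls, and the block coverage stayed at 84.8%. Coverage of Cγ1 rose from 5.55% ± 0.648 to 11.3% ± 1.96, by 5.75 points, and 149 of 64850 tiles rose as much. NIPBL coverage was also higher without overlap in the 3'RR (the enhancer cluster at the 3' end of Igh; 3.00% ± 0.121 to 5.53% ± 1.23), in the interval between Cγ3 and Cδ (0.280% ± 0.396 to 1.18% ± 0.334), in IGCR1 (0.570% ± 0.806 to 2.80% ± 0.728) and in the middle and distal VH segments (0.574% ± 0.00579 to 0.888% ± 0.175). Cμ-Sμ was lower (20.8% ± 6.96 to 14.1% ± 1.19), and 11 of the 17 segments overlapped (chance share separated 0.333). Outside Igh 9 of 15 loci were higher without overlap, Pax5, Ebf1 and Rag1/Rag2 (1.96% ± 0.612 to 4.23% ± 0.959) among them, so the rise was not confined to Igh. NIPBL regions gained outside the VH segments lay in the 3'RR (114479263 to 114479732), Eμ-JH (114665645 to 114665891, fold 3.85 to 5.64), Cγ2a/c (114532916 to 114533157), Cμ-Sμ (114660361 to 114660772) and the 3'CBEs (114456231 to 114456364), and 1 was lost in Cγ2a/c (114536209 to 114536591).

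**Figure D3:**
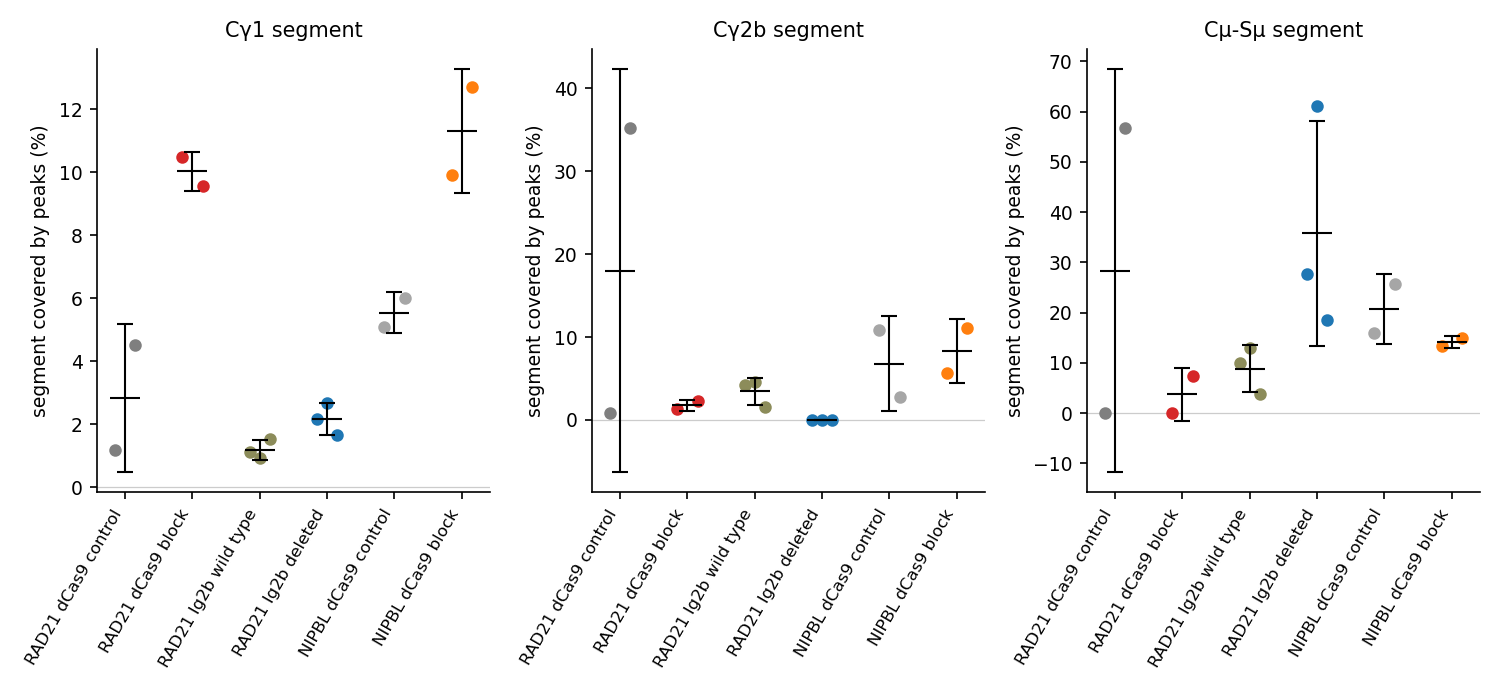
Share of the Cγ1, Cγ2b and Cμ-Sμ segments covered by peaks (%) in each library (points), with the mean and SD of each group (black). Cγ1 coverage rose with the block from 2.84% to 10.0% for RAD21 and from 5.55% to 11.3% for NIPBL, and Cγ2b coverage was 0% in the 3 deleted libraries.

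Of 14652 windows tested for NIPBL, limma called 0, with 1501 under an unadjusted p of 0.05 (1236 higher and 265 lower with the block; median log2 shift of all windows 0.12). The split was 747 higher and 632 lower with quantile normalization, and 409 higher and 710 lower without NIPBL dCas9 block replicate 2. The Sγ1 window had a log2 difference of 0.77 (SE 0.17, limma adjusted p 0.467, higher in 2 of 2 block libraries). The stricter threshold called 34 windows (27 higher, 7 lower), and there the Sγ1 window had a log2 difference of 2.22 and a limma adjusted p of 0.126 (0.126 to 0.812 over its alternatives). Cγ1 coverage had an exact two-sided permutation p of 0.333, the smallest possible, and 0.944 after adjustment over the list alone. Gained and lost regions numbered 5927 and 3935 of 238985, 9862 together, against 8933 and 8376 for the other splits, 1512 at a stricter threshold and 31450 to 80033 without any 1 of the 4 libraries. Regions gained by both proteins numbered 10, where independent gains would have given 13.5, and regions lost by both numbered 2, against 0.518; the Sγ1 region was not among the gained because NIPBL already had a peak there. Whether the block acted differently on RAD21 and NIPBL was tested as an interaction in 13452 windows: limma called 0 (48 under an unadjusted p of 0.05). The Sγ1 window again ranked 1, with a NIPBL change smaller than that of RAD21 by a log2 of −1.95 (SE 0.36, limma adjusted p 1, and 0.599 to 1 over its alternatives). At the stricter threshold, where the interaction was not fitted, the separate log2 differences lay closer, at 2.66 for RAD21 and 2.22 for NIPBL.

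The fourth question was what the Ig2b deletion did to cohesin. A RAD21 peak at Iγ2b, on chromosome 12 from 114552680 to 114553251 (intergenic, 6536 to 7107 bp upstream of the annotated start of Ighg), was present in 3 of 3 wild type and 0 of 3 deleted libraries. It covered 425, 402 and 273 bp in the wild type libraries, 64.1% ± 14.3 of the region (fold 4.07 to 4.82; SD, n = 3). The 4 RAD21 and 4 NIPBL libraries of the dCas9 experiment also had a peak there. At a stricter threshold 2 of 3 wild type libraries kept it. Coverage of the Cγ2b segment went from 3.44% ± 1.60 to 0% (n = 3 each), a difference of −3.44 points, of −1.62 at the stricter threshold and of −1.20 with both ends moved out by 3 kb. The coverage cannot separate lost binding from lost DNA, since a deleted sequence yields no reads. The next RAD21 peak toward Cγ1, inside the Cγ1 segment, was present in every RAD21 library.

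RAD21 coverage was higher in the deleted libraries, without overlap, at Cμ-Sμ (8.85% ± 4.70 to 35.8% ± 22.4), the 3'CBEs (9.71% ± 0.711 to 13.5% ± 2.02), the 3'RR (0.896% ± 0.795 to 1.97% ± 0.446), Cα (0.262% ± 0.454 to 1.26% ± 0.266) and Cγ1 (1.20% ± 0.319 to 2.17% ± 0.513). For Cμ-Sμ 3 of 66012 tiles rose as much, and a region from 114658096 to 114658559 near Gm11029 was gained there (fold 3.38 to 4.03). The remaining 11 of 17 segments overlapped, where chance separates 10% of comparisons of 3 against 3. Across the 3 deleted libraries Cμ-Sμ coverage was 18.5% to 61.1%. The dCas9 controls, of the wild type genotype by the labels, differed from each other there by more than these group means did. The deleted lists also covered more of the genome, 18.4 ± 6.61 Mb against 13.7 ± 1.87 Mb in the wild type (SD, n = 3 each). Outside Igh, Ebf1 (1.62% ± 0.346 to 3.36% ± 1.47) and Hoxb were higher.

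The Cγ2b loss had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, and 0.283 after adjustment over the list alone. Among 8119 windows limma called 0, with 897 under an unadjusted p of 0.05 (839 higher and 58 lower in deleted cells). The median log2 shift of all windows was 0.23. With quantile normalization, which removes that shift, the split became 574 higher and 492 lower. It also depended on single libraries. Without RAD21 Ig2b deleted replicate 2 it was 298 higher and 191 lower (median shift 0.096). Without RAD21 Ig2b deleted replicate 3 it was 2872 higher and 36 lower (median shift 0.378). The Iγ2b window, which also held that retained Cγ1 peak, had a log2 difference of −0.14 (SE 0.16, limma adjusted p 0.646). Alternatives called 43 windows at a stricter threshold (42 higher), 10 with quantile normalization (4 higher) and 6 with lists matched in length (0 higher), and the Iγ2b window was not called in the latter pair and not tested at the stricter threshold. Of the 10 with quantile normalization 1 lay in the proximal VH segments (114900001 to 114910000), lower in deleted cells by a log2 of −1.54. Gained and lost regions numbered 981 and 201 of 105335, 1182 together, against 306 to 1567 for the other 9 splits of the 6 libraries and 1914 to 4428 without any 1 library. With lists matched in length 597 were gained and 434 lost, and at a stricter threshold 885 and 29. Of the gained regions, 288 of 981 (29.4%) had a peak in each of the 4 RAD21 libraries of the dCas9 experiment.

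**Figure D4:**
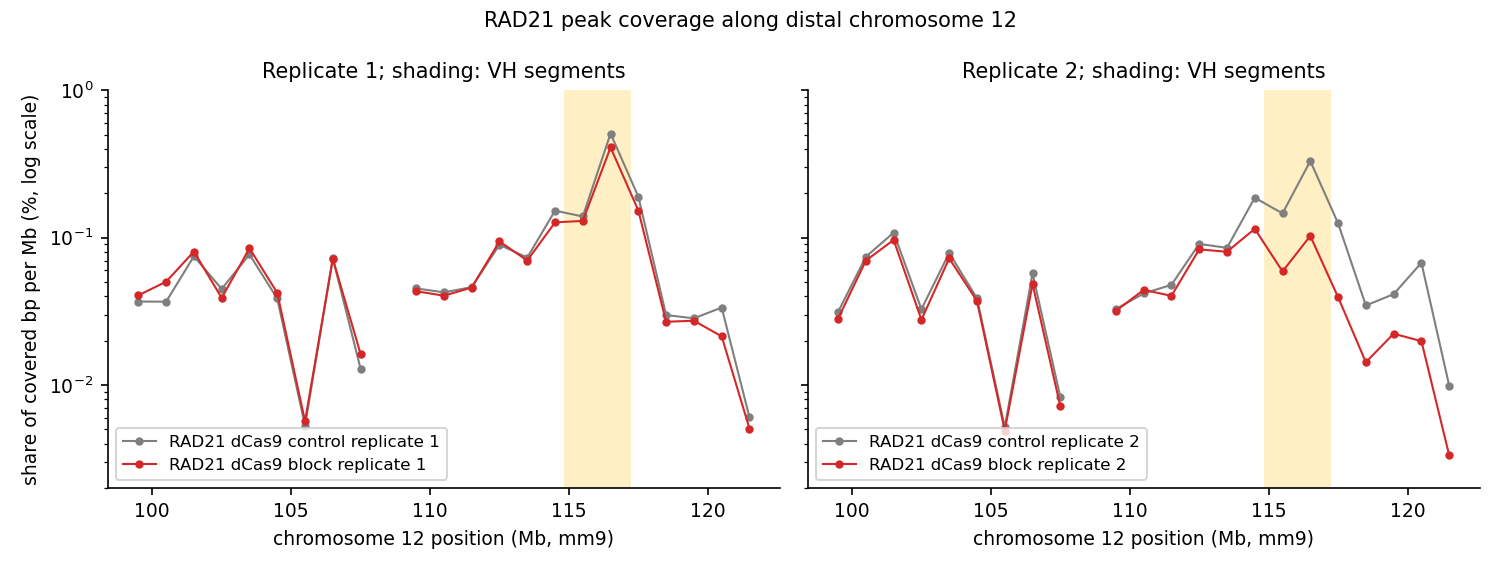
Share of each RAD21 dCas9 library's covered bp that lay in each Mb of chromosome 12 (%, log scale) against position (Mb), for replicate 1 (left) and replicate 2 (right); grey is control, red is block and shading marks the VH segments. In replicate 2 the block line runs below the control line from the VH segments to the end of the chromosome, with covered bp ratios of 0.300 over VH and 0.376 past it.

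Wild type cells of the Ig2b experiment and dCas9 controls had 1 genotype by the labels, which gave a measure of the difference between experiments. Of 9895 windows limma called 0, with 1118 under an unadjusted p of 0.05 (74 higher and 1044 lower in the Ig2b wild type; median log2 shift −0.42). Without RAD21 dCas9 control replicate 1 it called 6802 (384 higher, 6418 lower). Without RAD21 dCas9 control replicate 2 it called 0, with 677 higher and 583 lower under an unadjusted p of 0.05 and a median log2 shift of −0.05, so the shift rested on that library. Regions present in 1 group and absent from the other numbered 347 and 5850, against at most 3860 for the other splits. Cell set, experiment and peak calling cannot be told apart here, since each experiment held 1 of these groups. By their peak names the Ig2b lists had no control library and had duplicates taken out. The dCas9 lists named a control library and no removal of duplicates.

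The lists of a group were not more alike than those of different groups in the RAD21 dCas9 set: the mean Jaccard index was 0.360 within and 0.454 between groups, and 0.545 between libraries of the same replicate number (exact one-sided permutation p 1, smallest possible 0.333). It was 0.362 within and 0.352 between for NIPBL (exact p 0.333) and 0.478 within and 0.460 between for the Ig2b set (exact p 0.3, smallest possible 0.1). With lists matched in length the Ig2b set had 0.527 within and 0.503 between (exact one-sided permutation p 0.1).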

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

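No result met the rules for a closer look. These asked for a library far from the others of its group, an effect of the block that differed between RAD21 and NIPBL, or a signal outside the main measurement. The groups of 2 or 3 libraries were too small for the first. The second was tested in 13452 windows and in 32 segments and loci, of which 0 moved in opposite directions without overlap. For the last, peaks on the Y chromosome (35 to 176 per library) and the mitochondrial chromosome (1 to 18) were compared in 6 ways. For the patterns weighed here, the tests on matched list lengths and on other splits were set before the results were seen; those on the Ig2b libraries, on replicate numbers, on missing DNA and on the chromosome 12 flanks were chosen after.

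The first pattern is the RAD21 peak at Sγ1. Longer lists in the block libraries are argued against, since with lists matched in length the block libraries still covered 97.1% of the region. Both controls had no peak, which was fixed beforehand, since matching only shortens lists. A repeated sequence that gives a peak in any RAD21 library is argued against by the 6 Ig2b RAD21 libraries. They did not enter the choice of the region, and 0 of them had a peak there. Their lists named no control library and had duplicates taken out, unlike the dCas9 lists, which limits this argument. Each naming style held 1 control and 1 block library, and in each the block library had the peak and the control did not. A batch of peak names was thus balanced between the groups. With naming style in the fit as a block, the Sγ1 window was the only 1 of 16780 called (limma adjusted p 2.45e-06, log2 2.72, higher in 2 of 2 block libraries, range 2.45e-06 to 1 over the alternatives). In a balanced design the block cannot change the log2 difference, so this fit does not test the batch as a cause. The guide in dCas9-expressing cells is the biological difference the design names, and a block that holds cohesin at Sγ1 remains a hypothesis, since RAD21 at dCas9 on another target was not measured in these libraries.

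The second pattern is the RAD21 peak at Iγ2b that was missing from the 3 deleted libraries. Shorter lists are argued against by their lengths, 60110, 75679 and 44783 peaks in the deleted libraries and 50913, 56443 and 45782 in the wild type. With matched lists the wild type libraries still covered 64.1% of the region and 0 deleted libraries had a peak. The latter was fixed beforehand, since matching only shortens lists. Absence of the DNA itself and loss of cohesin binding cannot be told apart: the deleted libraries had 0 peaks in the whole Cγ2b segment, the ends of the deletion are not stated, and a deleted sequence gives no reads. At the scale of all windows, the 10 splits of the 6 Ig2b libraries are too few for a share under 0.05; the real split called 0 windows, the highest of the others called 0, and so 10 of 10 gave as many. At an unadjusted p under 0.05 the real split had 897 windows and the highest other 1815.

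The third pattern is the low RAD21 coverage of the VH segments in block replicate 2. A shorter list is argued against, since the ratio to control replicate 2 was 0.300 over VH and 0.916 over the genome. Whether the loss stops at VH or runs on to the end of chromosome 12, as fewer DNA copies would give, cannot be told apart: over the flank toward the telomere the library lay at percentile 0.155 of tiles against control replicate 2, which was itself high there against the 2 other dCas9 libraries, but at 12.8 against control replicate 1 and 13.6 against block replicate 1, while the flank on the other side of Igh lay at percentile 7.42 against control replicate 2. An effect of the block on RAD21 in either replicate also stays open, since VH in replicate 1 lay at percentile 3.802, between the bounds set for either answer. NIPBL coverage of VH, in other libraries, rose with the block relative to the genome (ratios of 1.31 against 0.903 and 1.75 against 1.38), so no loss there was seen with NIPBL. Its peaks covered only 12051 and 12367 bp of VH in the controls, against 135346 and 205153 bp for RAD21. Coverage this low left little room for a loss to show.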

How the results depend on the processing

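Of 159 values recomputed under another setting, 124 were labelled kept, 30 moved, 5 passed the threshold where the reported value did not, and 0 reversed. A count of windows or regions was kept when close to the reported total, whatever its direction, so no count could be labelled reversed. The RAD21 block regions, 1475 gained and 355 lost by default and 275 and 303 at the stricter threshold, thus counted as moved. Co-occupancy was kept while above the shifts and on the same side of the threshold, whatever its size. Coverage differences were kept within the spread, and the rest by direction or side of the threshold. The combinations of the replicate block with another setting were chosen after seeing the data. Except where stated, the cause was not tested.

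The RAD21 block comparison called 0 windows by default and 1, that of Sγ1, with the replicate block, with the block and matched lists, with the block and quantile normalization, with the block and 100 bp added, and with all 10 RAD21 libraries; limma adjusted p for that window ranged from 2.45e-06 to 1 over the alternatives, while its log2 difference without any 1 library stayed at 2.68 to 2.75 and in windows of 50 kb was 0.89 (SE 0.74, rank 284). With all 10 libraries its SE was 0.17, where the 6 Ig2b libraries have 0 bp and add no spread. The replicate block with the stricter threshold called 0 (log2 2.66, adjusted p 0.448). The split of these 4 libraries by number called 6196 windows, where the other 2 splits, the real one included, called 0. This points to a structure of the samples that follows number and naming style. With the block the SE of the Sγ1 window went from 0.32 to 0.27 at the same log2 difference. The fall in its adjusted p rested mainly on the degrees of freedom that limma borrowed from other windows. These went from 2.53 to 25.8, while the residual ones went from 2 to 1. With the block and the stricter threshold 3.88 were borrowed, and the window was not called. In the NIPBL and Ig2b sets the libraries shared only a number, with same-number r of 0.206 and of 0.0473 to 0.215, and the replicate block called 0 windows in each (1641 and 1809 under an unadjusted p of 0.05). The replicate block changed no other call.

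The stricter threshold called 34 windows for NIPBL and 43 for Ig2b. Quantile normalization called 10 for Ig2b and matched lists 6. Ig2b wild type against dCas9 control gave 0 to 6802 windows without 1 library, the highest without RAD21 dCas9 control replicate 1. Gained and lost regions at the stricter threshold were 578 for the RAD21 block and 1512 for NIPBL. Without 1 library they were 13068 to 25482, 31450 to 80033 and, for Ig2b, 1914 to 4428, all higher because fewer libraries must share a state. The Cγ1 difference was 11.03 points for RAD21 with ends moved in (5.52 to 8.84 without 1 library) and 8.36 for NIPBL at the stricter threshold (4.37 to 7.14). The Cγ2b difference was −1.62 at the stricter threshold and −1.20 with ends moved out, which adds covered bp outside the segment (−4.36 to −2.89). Co-occupancy was 9.42% to 44.3% without 1 library.

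The threshold of the caller limits these lists, since a region without a peak may hold signal under it. At Sγ1 NIPBL control coverage was 42.9% at the authors' threshold and 3.86% at the stricter one, where the Cγ1 difference grew to 8.36 points. Read depth was unknown, so its part was not tested.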

Other observations

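Among the tests described here, the count of repeated protospacers was set before its result was seen, and every other value was chosen for description after the data were seen. The RAD21 regions gained in Ig2b deleted cells with the highest fold lay outside Igh. The first was on chromosome 6 from 16500110 to 16500917 (mean fold 11.1 ± 0.809, SD, n = 3; intergenic, 348 kb from the start of Tcfec), and a second lay 101 kb from Tcfec, from 16747690 to 16748035 (fold 6.70 to 8.73). Neither held a CTCF core, and 0 of the 4 dCas9 RAD21 libraries had a peak at either. Gained regions inside Iqcj (fold 6.11 to 6.12) and Robo2 (5.29 to 6.74) had peaks in 2 and 3 of those 4 libraries. The lost regions near Steap3 (4.98 to 5.97) and inside Acvr1c (4.69 to 4.83) and B3gat2 (4.11 to 6.06) had peaks in all 4 dCas9 libraries, as did Iγ2b. Of the 201 lost regions 50 (24.9%) had a peak in all 4 and 43 (21.4%) in none.

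For NIPBL the gained regions with the highest fold lay inside Cyth1 (4.89 to 5.12), where 8 of 10 RAD21 libraries had a peak, and near Myl10 (4.58 to 4.89), where 10 of 10 had one over a CTCF core. The lost region with the highest fold lay inside Dpp9 (7.21 to 8.69), with 0 of 10 RAD21 libraries. Among block libraries 29.3% of NIPBL regions overlapped RAD21, against 2.24% after shifting. CTCF cores lay in 7.34% of the regions gained and 1.99% of those lost in Ig2b deleted cells. Each of the 14 lists had a peak of 38334 to 38349 bp at the start of chromosome 9 (2999990 to 3038339 at its outermost ends), with folds of 27.8 to 57.1. In 3 lists (RAD21 block replicates 1 and 2 and Ig2b deleted replicate 1) another peak was wider, at 71015, 60429 and 69539 bp.

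The width of the RAD21 peak at Sγ1 raised the question whether 1 guide could bind there many times. Switch regions are tandem repeats, and the guide sequence is not stated. In the Cγ1 segment 33 sequences of 20 bp occurred at least 4 times next to an NGG, at 232 sites, and 229 of these (98.7%) lay in the gained region, which makes up 8.77% of the segment. The repeated sites ran from 114572680 to 114576799, with up to 16 copies of 1 sequence. A single guide could thus place dCas9 at many sites along the peak, but the count does not show which sequence was used. Since switch regions are repeats, any peak over Sγ1 would hold many such sites, and other segments were not searched.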
